A study of Rattus norvegicus with 4 samples.

How the data were processed

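Gene expression had been measured on 4 Affymetrix rat expression arrays, each hybridised with total RNA from 1 sample of neonatal rat ventricular myocytes. Per the labels, control replicates 1 and 2 came from uncoated dishes, and fibronectin replicates 1 and 2 came from dishes coated with fibronectin. The deposited table held 1 signal intensity per probe set and array on a linear scale. How the authors made these intensities from the scanned images, and which scaling target they used, is not given in the sources used here.

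The deposited intensities themselves show that each array other than control replicate 1 had been multiplied by its own constant. On all 4 arrays, 100% of the values below 200 steps lay within 0.05 steps of a whole multiple of a step. The step was 0.1 on control replicate 1, 0.233 on control replicate 2, 0.223 on fibronectin replicate 1 and 1.95 on fibronectin replicate 2. On control replicate 1 the step could come from rounding alone. The median intensity thus spanned 1107, 390, 494 and 50 steps in that order, so dim values were coarsest on fibronectin replicate 2. Trimmed means, which left out 2% of values at each end, were 219.8, 175.0, 247.3 and 175.0. They differed by more than 10%, so the arrays were quantile normalized before testing. No detection calls were used. For arrays, their number limits the precision, and it was 2 per group.

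Normalized intensities were raised to a floor of 23.4, the 20th percentile of all values, and converted to log2. Values at the floor have no order, and a fold against a group at the floor on both arrays is given as a lower bound. The table held 15875 probe sets, of which 9 Affymetrix control probe sets were left out. The 40% of the rest with the lowest mean log2 signal over the 4 arrays, 6347 probe sets, were left out as dim, and 9519 were tested. Gene names came from the platform annotation supplied for this work, in which 12783 probe sets had 1 gene symbol, 312 had several and 2771 had none. Entrez identifiers of 12748 of the named probe sets were found in the gene table of the GRCr8 assembly, and 0 symbols needed updating. Only probe sets with 1 symbol were named. The array files carry no genome coordinates, and none are given.

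Fibronectin and control arrays were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3. The p-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Probe sets that differed by at least 1 on the log2 scale without overlap between the groups were counted as a description of size. With 2 arrays against 2, 33.3% of unchanged probe sets do not overlap, and the smallest two-sided p of an exact permutation test is 0.333. Errors beside log2 differences are limma's moderated standard errors.

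Lists of genes for pathways, complexes and cell types were tested with camera in limma on 7101 genes, each represented by its brightest tested probe set. Camera was run with a preset correlation of 0.01 between genes, and repeated with a correlation estimated per list. Of 36 lists, 35 had the required 5 measured genes. Members were also counted by limma's adjusted p over all genes and by p-values adjusted over the list alone. Among the lists were 8 for cell types other than ventricular myocytes. The groups, tests, gene lists, other settings to try and the rule for naming genes were fixed before the data were examined.

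That rule took, in each direction, up to 12 genes past the threshold and filled empty places with the named genes of largest difference whose groups did not overlap. It added Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Fn1, Itgb1 and Itga5. For each list that passed in camera it added up to 3 members with the smallest p in the list's direction and 1 against it. As no gene passed, all 24 places were filled by size.

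Ratios of 3' to 5' signal were taken on the deposited scale from the Affymetrix control probe sets for Gapdh, beta-actin and hexokinase. Alternatives were the deposited scale, a shift of each array to the same median, no filter, a stricter filter leaving out 60%, no floor, and an offset of 50 without a floor. Further alternatives were other variance models, a threshold of 0.10, the replicate number as a block, and leaving out each array in turn. For lists they were an estimated correlation, the rotation test fry, and the mean over all probe sets of a gene. Counts from the brightest probe set of each named gene alone were added after seeing the data.

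The limma test was tested on data simulated for 9519 probe sets with the measured spread, 200 of them shifted, in 20 simulations. It called 0.373% of probe sets shifted by 1 on the log2 scale, 10.4% of those shifted by 2, 41.2% of those shifted by 3 and 0.0258% of unshifted ones. The simulated probe sets varied independently, each with the same spread on all 4 arrays. The measured SD of log2 signals from each probe set's mean was 0.43 and 0.47 on control replicates 1 and 2. On fibronectin replicates 1 and 2 it was 0.48 and 0.70. The simulated shares may thus not hold for these arrays. For a list of 28 genes, 200 simulations were made per setting. A simulated list was called at an unadjusted p under 0.05, a looser rule than the adjusted threshold used for the results. With a correlation of 0.3 between genes and no shift, camera called 47.5% of lists with the preset correlation and 4.50% with an estimated one. With a shift of 0.8 it called 99% and 36% of them. With a correlation of 0 between genes and no shift, camera called 3.5% of lists with the preset correlation and 0% with an estimated one. With a correlation of 0 and a shift of 0.8 it called 100% and 96%.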

Results

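Neonatal rat ventricular myocytes, the contractile cells of the newborn heart kept in primary culture, were compared between uncoated dishes and dishes coated with fibronectin, a matrix glycoprotein that binds integrin receptors. All cells had 24 h in medium with 10% serum and then 48 h without serum. Each of the 2 groups had 2 arrays. Median signal was 111 on control replicate 1, 90.9 on control replicate 2, 110.4 on fibronectin replicate 1 and 97.4 on fibronectin replicate 2. Across the 9519 tested probe sets, which are not independent replicates, log2 signals correlated with r = 0.910 between the controls and 0.792 between the fibronectin arrays. Correlations between groups ran from 0.775 to 0.904. Fibronectin replicate 1 correlated with control replicates 1 and 2 at 0.904 and 0.847, more closely than with fibronectin replicate 2. That array stood apart, with 0.775 and 0.794 against control replicates 1 and 2, so the arrays did not group by coating. In the deposited table no probe set had an identical value on any pair of arrays. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

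The first comparison asked which transcripts differ between myocytes on fibronectin and on uncoated dishes, in a study whose title concerns hypertrophy. Natriuretic peptide and fetal actin transcripts had higher values on both fibronectin arrays than on both controls. Nppa, which encodes atrial natriuretic peptide, had a mean log2 signal of 13.30 ± 0.20 on fibronectin and 11.82 ± 0.93 on uncoated dishes (SD, n = 2 each), a 2.78-fold higher value. Nppb, which encodes B-type natriuretic peptide, measured 11.71 ± 0.85 on fibronectin and 10.55 ± 0.05 on uncoated dishes (SD, n = 2 each), 2.24-fold higher. Acta1, the skeletal alpha-actin of the fetal heart programme, measured 11.97 ± 0.25 and 11.16 ± 0.41 (SD, n = 2 each), 1.76-fold higher. None of the 3 passed limma's test with Benjamini-Hochberg adjustment. Their log2 differences were 1.48 (SE 0.42) for Nppa, 1.17 (SE 0.40) for Nppb and 0.81 (SE 0.30) for Acta1, with limma's Benjamini-Hochberg adjusted p = 0.684, 0.719 and 0.726. With 1 array left out the difference ran from 0.83 to 2.24 for Nppa and from 0.53 to 1.76 for Nppb. For Acta1 it ran from 0.54 to 1.12. The Gapdh control transcript had 3' to 5' ratios of 6.02 and 3.52 on these fibronectin arrays and 1.64 and 1.15 on the controls.

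Other contractile and adhesion genes chosen in advance did not share one direction. Myh7, the beta-myosin heavy chain, had 2 tested probe sets that disagreed. Its brighter probe set differed by 0.11 (SE 0.24), from 13.73 on uncoated dishes to 13.84 on fibronectin. Its dimmer probe set differed by -3.29 (SE 0.68), 9.77-fold lower on fibronectin. Myh6, the alpha-myosin heavy chain, differed by 0.25 (SE 0.44) in its tested probe set. Its other probe set, left out as dim, differed by -1.44, with fibronectin replicate 2 at the floor. The 3 tested probe sets of Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by -0.94 (SE 0.32), -0.35 (SE 0.29) and -1.53 (SE 0.78), from brightest to dimmest. Fn1, the cells' own fibronectin transcript, differed by -0.60 (SE 0.26), 1.51-fold lower in the coated dishes. Itgb1, the beta-1 integrin subunit of the main fibronectin receptor, differed by -0.77 (SE 0.30) in its brighter and -1.86 (SE 0.44) in its dimmer probe set. In the annotation used here no probe set carried the name of Itga5, the alpha subunit of that receptor, which was not analysed here. None of the tested probe sets of these genes passed limma's test with Benjamini-Hochberg adjustment, the lowest adjusted p being 0.529 for the dimmer Myh7 probe set. On the deposited scale without further normalization the difference was 0.83 for the brighter Myh7 probe set, -0.15 for Fn1 and -0.33 for the brightest Atp2a2 probe set. Depending on the array left out, the difference ran from -0.06 (without control replicate 1) to 0.29 for the brighter Myh7 probe set, from -0.38 (without fibronectin replicate 1) to 0.86 for Myh6, from -1.33 to -0.59, -0.51 to -0.17 and -2.73 to -0.25 for the Atp2a2 probe sets in the same order, and from -1.02 to -0.50 for the brighter Itgb1 probe set.

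**Figure D1:**
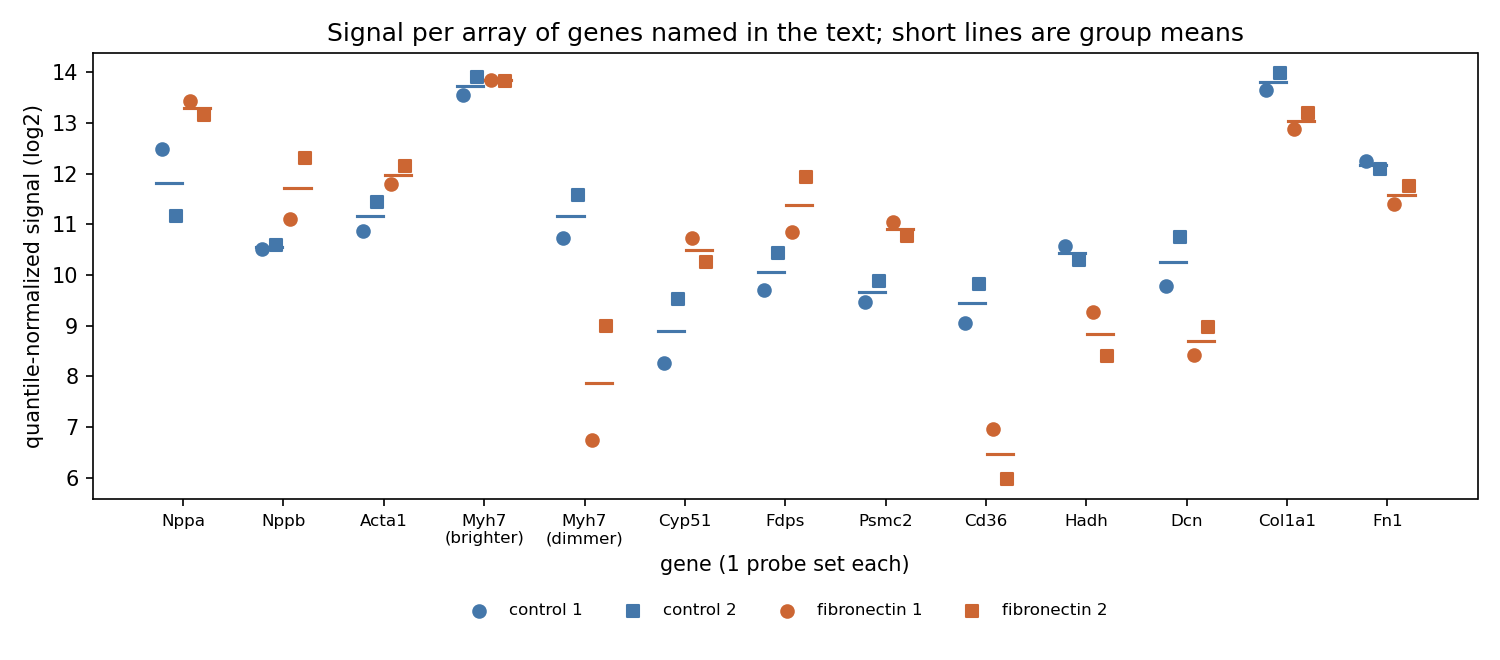
Quantile-normalized log2 signal on each of the 4 arrays for named genes, with 1 probe set per column; blue marks are control arrays, orange marks fibronectin arrays, and short lines are group means. Nppa, Nppb and Acta1 lie higher on both fibronectin arrays, Cd36, Hadh and Dcn lie lower, and the brighter and dimmer Myh7 probe sets differ by 0.11 and -3.29.

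The largest higher values among named genes without overlap belonged mostly to transcripts that were dim on the controls. Stat2, a transducer of interferon signals, was at the floor on both control arrays and measured 7.62 ± 0.69 on fibronectin (SD, n = 2), at least 8.40-fold higher, while its brighter probe set differed by -0.29. Thoc3, a subunit of the mRNA export complex THO, was at the floor of 4.55 on 1 control array and at 4.57 on the other, against 7.47 on fibronectin, so the size of its difference is not measured. Inf2, a formin that remodels actin filaments, differed by 2.46 (SE 0.55), from 5.31 to 7.76. The sterol demethylase Cyp51 differed by 2.12 (SE 0.55) in this probe set and by 1.60 (SE 0.45) in a brighter one. Stmn3, a microtubule-destabilizing protein, differed by 2.51 (SE 0.84), and Xylt2, a xylosyltransferase of proteoglycan synthesis, by 2.41 (SE 0.67), with -0.27 in another tested probe set. A further Xylt2 probe set, left out as dim, differed by -1.46. Tmem259 differed by 2.12 (SE 0.76), with -1.13 in another probe set. Mrto4, 6330403K07Rikl, Mon1b, the sulfiredoxin gene Srxn1 and Spata13 completed the 12 with differences of 2.00, 1.99, 1.94, 1.90 and 1.89. For Stmn3, Xylt2, Mrto4, 6330403K07Rikl and Mon1b 1 control array was at the floor. Leaving out 1 array gave differences from 0.98 to 3.34 for Tmem259, from 0.94 to 3.11 for Mrto4, from 0.90 to 3.14 for 6330403K07Rikl, from 1.24 to 2.72 for Mon1b and from 1.06 to 2.79 for Srxn1, with each of these lowest and highest values found with 1 of the controls left out.

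The largest values in the lower direction often came from a single probe set of a gene measured elsewhere. Cct6a, a chaperonin subunit, was at the floor on both fibronectin arrays, at least 16.0-fold lower than its control value of 8.55, while its other probe set differed by -0.44. Pfkm, the muscle phosphofructokinase, had a probe set at 8.44 on the controls and at 4.84 and 4.71 on the fibronectin arrays, so near the floor of 4.55 that the size of its difference is not measured, and differed by -0.21 in the other. Probe sets also disagreed for Myo1c, an unconventional myosin, at -3.54 (SE 0.74) against 0.08. They disagreed too for Gja1, the gap junction protein connexin 43, at -3.20 (SE 0.68) against -0.07. The dimmer Gja1 probe set read 4.93 and 5.50 on the fibronectin arrays, close to the floor, so its size is uncertain. Tpm4, a tropomyosin, differed by -3.26 (SE 0.61) against -0.70, and Polr2m, a subunit linked to RNA polymerase II, by -2.99 (SE 0.60) against 0.11. Emp1 was at the floor on both fibronectin arrays, at least 8.45-fold lower, against -0.21 in its other probe set. Canx, the chaperone calnexin, differed by -3.37 (SE 0.86) against -0.47 and -1.04, and Cs, citrate synthase, by -3.04 (SE 0.83) against -0.81 and -0.98. Of the 12 genes, 10 had a brighter tested probe set, counting Myh7, and the brightest ones differed by -0.81 to 0.11 with a median of -0.21. The remaining genes, the fatty acid transporter Cd36 at -2.97 (SE 0.48) and the organic anion transporter Abcc3 at -3.02 (SE 0.67), had 1 tested probe set each. For Myo1c, Canx, Abcc3 and Polr2m 1 fibronectin array was at the floor, and without fibronectin replicate 1 the difference was -2.34 for Myo1c and -1.55 for Cs.

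In limma's test 0 of 9519 probe sets passed the Benjamini-Hochberg threshold, and the lowest adjusted p was 0.476. At an unadjusted p under 0.05 there were 616 probe sets, 253 higher and 363 lower on fibronectin, where chance gives 476. Counted once per gene by its brightest probe set, 227 of 7101 genes were higher and 203 lower at that p. A difference of at least 1 on the log2 scale without overlap was found for 877 probe sets, 326 higher and 551 lower. Over all sizes, 38.2% of probe sets did not overlap, against 33.3% by chance. With the arrays split by replicate number instead of coating, limma gave 671 probe sets at an unadjusted p under 0.05. The remaining split into pairs gave 55. The excess of 616 over 476 thus does not set the coating apart. Leaving out 1 array changed the number past the threshold to 6 without control replicate 1, 17 without fibronectin replicate 2 and 459 without fibronectin replicate 1, in fits that assume the lone array varies like the other group. Of the named probe sets, 3, 5 and 18 passed in those fits, among them the dimmer Myh7 probe set in each. The number of large differences was 1353 without control replicate 1 and 2211 without fibronectin replicate 1, and ran from 338 to 1586 with other filters on dim probe sets, an offset or 1 probe set per gene, where 252 were higher and 286 lower.

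The second comparison asked which groups of genes shifted together. Genes of sterol and fatty acid synthesis gave the smallest p of the 35 lists in camera with the preset correlation, with higher values on fibronectin for 27 of 28 measured members and a median log2 difference of 0.81. This camera test gave a Benjamini-Hochberg adjusted p = 1.71e-08, and adjusted p = 0.652 with an estimated correlation. Cyp51, lanosterol demethylase, differed by 1.60 (SE 0.45), and Fdps, which makes farnesyl diphosphate, by 1.32 (SE 0.42). Sc5d, a sterol desaturase, differed by 1.37 (SE 0.41), with -0.16 in a dimmer probe set. Against them, Insig2, which retains the sterol-sensing machinery in the endoplasmic reticulum, differed by -0.48 (SE 0.59). Both fibronectin arrays exceeded both controls for 16 members, and 1 member lay below both. Relative to the control mean of each gene, the list's median was -0.31 and 0.31 on the control arrays, 0.53 on fibronectin replicate 1 and 1.22 on fibronectin replicate 2. No member passed limma's Benjamini-Hochberg threshold over all genes, and 0 passed when adjusted over the list alone, with a lowest adjusted p of 0.110. The difference was 0.98 for the brighter Cyp51 probe set without control replicate 1, 0.73 for Fdps and -0.25 for Insig2 without fibronectin replicate 2. The Gapdh control transcript had 3' to 5' ratios of 6.02 and 3.52 on these fibronectin arrays and 1.64 and 1.15 on the controls.

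The proteasome and ubiquitin list, whose measured members are subunits of the proteasome, the complex that degrades ubiquitin-tagged proteins, and the ubiquitin ligase Trim63, was higher on fibronectin for 22 of 27 members, with a median of 0.28. Camera gave a Benjamini-Hochberg adjusted p = 0.00610, and adjusted p = 0.652 with an estimated correlation. Psmc2, an ATPase of the regulatory particle, differed by 1.23 (SE 0.30), and Psmd13, another regulatory subunit, by 1.28 (SE 0.45). Psmb4, a subunit of the catalytic core, differed by 0.65 (SE 0.27), whereas Psma2, also of the core, differed by -0.53 (SE 0.29). Adjusted over the list alone, 0 members passed, as over all genes. Camera's Benjamini-Hochberg adjusted p was 0.211 without control replicate 1, 0.0912 without fibronectin replicate 1 and 0.108 without fibronectin replicate 2, where Psmd13 differed by 0.81. Beta-actin had 3' to 5' ratios of 13.0 and 6.29 on the fibronectin arrays and 1.46 and 1.40 on the controls.

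Genes of structural matrix proteins were lower on fibronectin for 24 of 32 measured members, with a median of -0.38. Camera gave a Benjamini-Hochberg adjusted p = 0.00139, and adjusted p = 0.652 with an estimated correlation. The estimated correlation was -0.0065, below the preset 0.01, so correlation between the genes does not account for the larger p. Dcn, the proteoglycan decorin, differed by -1.57 (SE 0.40), and Col4a1, a basement membrane collagen, by -0.83 (SE 0.31), or -0.51 without control replicate 1. Col1a1, the main fibrillar collagen, differed by -0.78 (SE 0.27), from 13.81 to 13.04, but by only -0.05 on the deposited scale. Fbln2, a fibulin, differed by 0.64 (SE 0.29). Both fibronectin arrays lay below both controls for 13 members and above them for 2, and 0 passed limma's Benjamini-Hochberg threshold over all genes or adjusted over the list alone. Fibroblast markers, which share 5 genes with this list, moved the same way, with 13 of 19 measured members lower and a median of -0.57. For them camera gave a Benjamini-Hochberg adjusted p = 0.00610, and adjusted p = 0.652 with an estimated correlation. Ogn, the small proteoglycan osteoglycin, differed by -1.56 (SE 0.33) and was lower in all 4 of its tested probe sets. Against the direction, S100a4, a calcium-binding protein of motile fibroblasts, differed by 0.51 (SE 0.25). Ogn and Dcn were the 2 members that passed when adjusted over the list alone, with a lowest limma Benjamini-Hochberg adjusted p of 0.0272, and 0 passed over all genes. On the deposited scale camera's Benjamini-Hochberg adjusted p was 0.0525 for matrix and 0.120 for fibroblast genes, and without fibronectin replicate 1 it was 0.423 for both, while without control replicate 2 it was 0.214 for fibroblast genes. These lower values came from arrays with Gapdh 3' to 5' ratios of 6.02 and 3.52, against 1.64 and 1.15 on the controls.

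Markers of leukocytes, chiefly macrophages, were also lower on fibronectin, in 10 of 12 measured members with a median of -0.50. Camera gave a Benjamini-Hochberg adjusted p = 0.0210, and adjusted p = 0.652 with an estimated correlation. Cd53, a leukocyte tetraspanin, differed by -1.28 (SE 0.54), and Lgals3, galectin-3, by -0.66 (SE 0.32). Aif1, a macrophage calcium-binding protein at the floor on fibronectin replicate 2, differed by -1.80 (SE 0.85), by -0.48 without that array and by -3.07 without fibronectin replicate 1. C1qa, a complement component made by macrophages, differed by 0.09 (SE 0.53), and its sign turned without control replicate 1 or fibronectin replicate 1. Neural and Schwann cell markers were higher in 6 of 6 measured members, with a median of 0.83, though the groups were free of overlap in only 2 of the 6. Relative to the control mean of each gene, this list's median was 0.37 and -0.37 on the control arrays, 0.14 on fibronectin replicate 1 and 1.34 on fibronectin replicate 2, so that fibronectin replicate 1 lay below control replicate 1. Camera gave them a Benjamini-Hochberg adjusted p = 0.0431, and adjusted p = 0.711 with an estimated correlation. The myelin enzyme gene Cnp differed by 1.01 (SE 0.36) but by -1.78 in its other tested probe set. Prph, the neuronal filament peripherin, differed by 1.65 (SE 0.80), or 1.02 without control replicate 2. Uchl1, a neuronal ubiquitin hydrolase that is also on the hypertrophy list, differed by 0.78 (SE 0.56) with overlapping groups, from 0.18 without control replicate 2 to 1.39 without control replicate 1. In both lists 0 members passed limma's Benjamini-Hochberg threshold over all genes or adjusted over the list alone. Camera's Benjamini-Hochberg adjusted p for the leukocyte list was 0.223 without control replicate 2, 0.553 without fibronectin replicate 1 and 0.162 with no filter on dim probe sets. For the neural list it was 0.112 on the deposited scale, 0.775 with no filter, 0.269 with the mean over all probe sets, 0.232 without control replicate 2 and 0.289 without fibronectin replicate 2. Beta-actin 3' to 5' ratios on the same fibronectin arrays were 13.0 and 6.29, against 1.46 and 1.40 on the controls.

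Immediate-early genes and feedback regulators of mitogen-activated protein kinases were lower on fibronectin for 22 of 30 measured members, with a median of -0.29. Camera gave a Benjamini-Hochberg adjusted p = 0.00610, and adjusted p = 0.652 with an estimated correlation. That correlation was -0.0135, below the preset 0.01. Zfp36, which promotes decay of short-lived mRNAs, differed by -1.67 (SE 0.41), and Id2, an inhibitor of DNA binding by helix-loop-helix factors, by -1.53 (SE 0.36). Dusp5, a nuclear phosphatase of ERK, differed by -0.88 (SE 0.40). Fos, a subunit of the transcription factor AP-1, differed by 1.17 (SE 0.67) at low signal, from 5.52 to 6.69. Genes of fatty acid uptake and oxidation were lower for 19 of 30 measured members, with a median of -0.28. Relative to the control mean of each gene, their median was 0.22 and -0.22 on the control arrays, 0.008 on fibronectin replicate 1 and -0.38 on fibronectin replicate 2, so that only fibronectin replicate 2 lay below both controls. For them camera gave a Benjamini-Hochberg adjusted p = 0.0399, and adjusted p = 0.744 with an estimated correlation. Cd36 at -2.97 (SE 0.47) and Hadh, a mitochondrial dehydrogenase of beta-oxidation, at -1.59 (SE 0.37) were the 2 members that passed when adjusted over the list alone, with a lowest limma Benjamini-Hochberg adjusted p of 0.00731. Etfdh, which passes electrons from beta-oxidation to ubiquinone, differed by -1.24 (SE 0.37), and Eci1, an enoyl-CoA isomerase, by 0.65 (SE 0.29). Over all genes 0 members of either list passed limma's Benjamini-Hochberg threshold, and 0 immediate-early members passed when adjusted over the list alone. Camera's Benjamini-Hochberg adjusted p for the immediate-early list was 0.103 without control replicate 2 and 0.115 without fibronectin replicate 1. For fatty acid oxidation it was 0.129 on the deposited scale, 0.108 with no filter, 0.640 without control replicate 1, 0.0749 without fibronectin replicate 1 and 0.104 without fibronectin replicate 2. Gapdh 3' to 5' ratios were 6.02 and 3.52 on the fibronectin arrays and 1.64 and 1.15 on the controls.

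**Figure D2:**
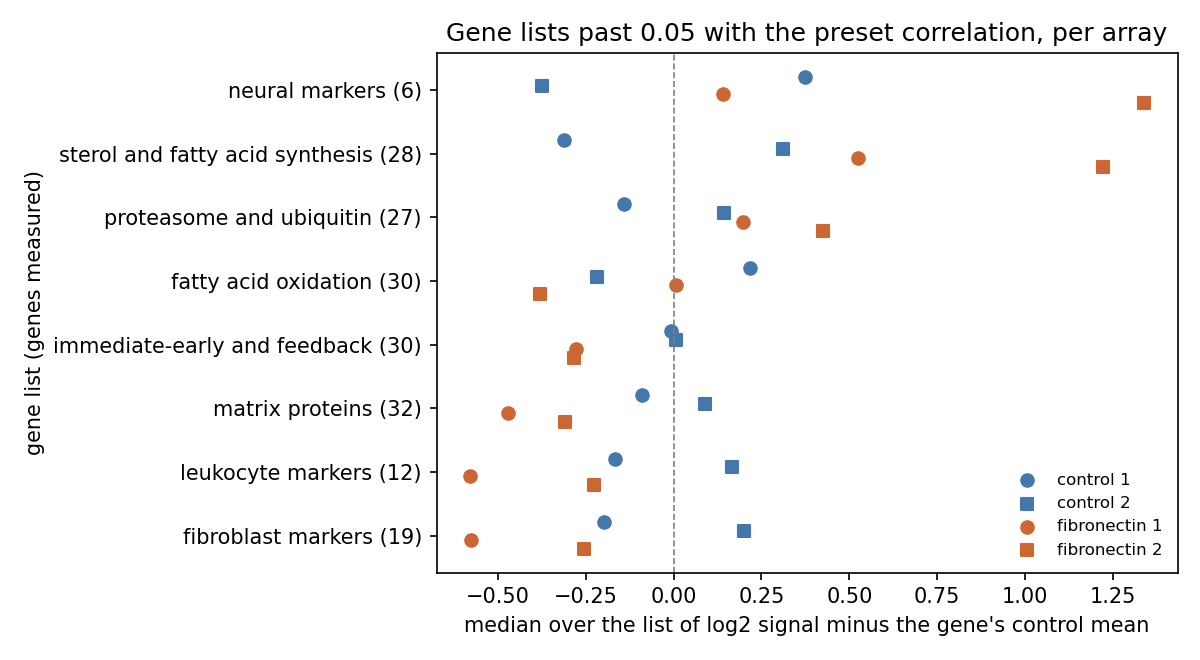
For each list past the threshold with the preset correlation, the median over its genes of log2 signal minus the gene's control mean on each of the 4 arrays; blue marks are control arrays and orange marks fibronectin arrays. Sterol and fatty acid synthesis stands at 0.53 and 1.22 on the fibronectin arrays and at -0.31 and 0.31 on the controls.

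The lists closest to the study's subject did not pass. Hypertrophy markers were higher on fibronectin for 17 of 25 measured members, with a median of 0.21, and camera's Benjamini-Hochberg adjusted p was 0.134. It was 6.44e-06 on the deposited scale, and 0.652 with an estimated correlation. Sarcomere genes were higher for 20 of 28 members, with a median of 0.17 and a camera Benjamini-Hochberg adjusted p of 0.149. It was 1.04e-06 on the deposited scale, and 0.652 with an estimated correlation. On the deposited scale camera also called the ribosomal protein list (Benjamini-Hochberg adjusted p = 1.72e-24) and the respiratory chain list (9.13e-05) as higher. Passing there was thus not particular to hypertrophy and sarcomere genes. Integrin and focal adhesion genes were lower for 18 of 31 members, with a median of -0.17 and a camera Benjamini-Hochberg adjusted p of 0.344, which was 0.0454 without control replicate 1 and 0.0485 without fibronectin replicate 2, while the direction turned to higher without control replicate 2 (0.939) or fibronectin replicate 1 (0.977). Calcium handling and ion channel genes were lower for 21 of 29, with a median of -0.20, a camera Benjamini-Hochberg adjusted p of 0.122, 0.00774 with the mean over all probe sets and 0.00685 without control replicate 2. Adult cardiac genes that usually decline in hypertrophy were split at 7 higher and 7 lower, and camera's Benjamini-Hochberg adjusted p was 0.797, with a median of 0.010, a mean of -0.05 and a lower direction in the test that turned on the deposited scale and without fibronectin replicate 2. In all, 8 of 35 lists passed with the preset correlation, 3 higher and 5 lower, against 0 with an estimated correlation and 0 in fry, whose lowest Benjamini-Hochberg adjusted p was 0.325.

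The third comparison set array quality side by side. Gapdh and beta-actin signals were much weaker at the 5' end of the transcript than at its 3' end on the fibronectin arrays, and less so on the controls. The 3' to 5' ratio of Gapdh was 1.64 and 1.15 on control replicates 1 and 2 and 6.02 and 3.52 on fibronectin replicates 1 and 2. For beta-actin it was 1.46 and 1.40 on the controls and 13.0 and 6.29 on fibronectin. Hexokinase, a dimmer control transcript, gave 3.77 and 4.12 on the controls and 3.11 and 7.0 on fibronectin, which overlap. After quantile normalization the fibronectin minus control difference of Gapdh was -0.63 for the 3' probe set, -1.25 for the middle and -2.14 for the 5' probe set. For beta-actin the corresponding differences were -0.96, -2.58 and -3.38. The ratios were described and not tested.

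**Figure D3:**
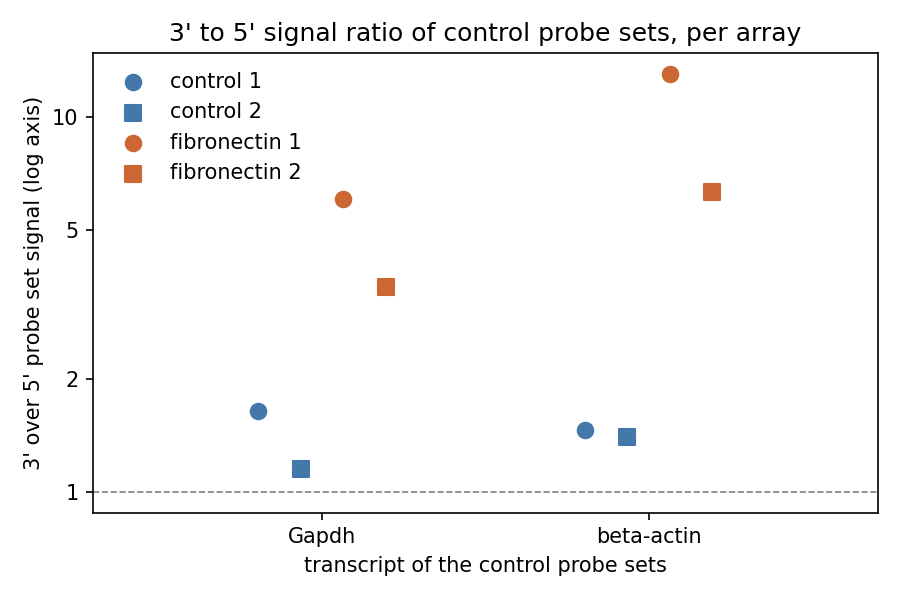
Ratio of 3' to 5' probe set signal of the Gapdh and beta-actin control transcripts on each of the 4 arrays, on a log axis; blue marks are control arrays, orange marks fibronectin arrays, and the dashed line marks a ratio of 1. The fibronectin arrays lie at 3.52 to 13.0 and the controls at 1.15 to 1.64.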

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

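All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. The first results to follow up are signal ratios of control probe sets, which no comparison of genes used. On the fibronectin arrays these ratios stood above those of both control arrays for Gapdh and beta-actin. The Gapdh 3' to 5' ratio was 6.02 on fibronectin replicate 1 and 3.52 on fibronectin replicate 2, against at most 1.64 on a control. The beta-actin ratio was 13.0 on fibronectin replicate 1 and 6.29 on fibronectin replicate 2, against at most 1.46 on a control. The ratios of hexokinase, a dimmer control transcript, overlapped between the groups.

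Many large lower values on fibronectin sat in 1 probe set of a gene whose other probe sets differed little. For each of 218 large lower probe sets, the median log2 difference over its gene's other tested probe sets was taken. These values had a median of -0.25 (bootstrap interval over probe sets, not arrays, -0.31 to -0.16), against -1.52 for the large probe sets themselves. This argues against lower transcript levels as the whole account. Noise in single probe sets picked for their size stays open. In the other direction, 48 large higher probe sets had a median of 1.25, against -0.09 for their genes' other probe sets taken in the same way. Over all 850 genes with more than 1 tested probe set, the median was -0.18 for the dimmer and -0.20 for the brighter probe set. The other probe sets in both directions thus lay near the level of such genes at large. Loss of 5' signal, from shorter RNA or shorter labelled target, may contribute and cannot be told apart from coating. The Gapdh and beta-actin ratios above separate the same arrays, and the positions of the other probe sets are not known here. Over 850 genes the dimmer probe set differed from the brighter by a median of -0.021 (interval -0.10 to 0.061), which decides nothing without those positions.

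The sterol and fatty acid synthesis list passed as higher on fibronectin with the preset correlation, at camera's Benjamini-Hochberg adjusted p = 1.71e-08, but at adjusted p = 0.652 with an estimated correlation and at 0.565 in fry. A relative gain of probe sets spared by 5' loss cannot be told apart from coating, judged by ribosomal protein genes, whose transcripts are short. The sterol median exceeded theirs by 0.68 after quantile normalization and by 0.19 on the deposited scale, where their own median was 0.67, and the controls differed in this excess by 0.56 and 0.27. Variation of the whole list between arrays of a group could account for much of the shift, because the controls differed from each other by a median of 0.62, against distances of 0.53 and 1.22 of the fibronectin arrays from the control mean. An effect of the coating stays open and untested beyond the comparison itself.

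The fibroblast marker and matrix lists passed as lower on fibronectin with the preset correlation, at camera's Benjamini-Hochberg adjusted p = 0.00610 and 0.00139, but at adjusted p = 0.652 for both with an estimated correlation and at 0.120 and 0.0525 on the deposited scale. A smaller share of fibroblasts would lower the markers alike only if fibroblasts alone made each marker and all probe sets responded alike. Around 1 common shift with the measured standard errors, 0% of 10000 simulations gave a spread as large as that of the 19 markers. The markers thus did not fall alike. Since neither condition was tested, this cannot decide whether the share of fibroblasts was smaller. Loss of 5' signal in these genes cannot be told apart from coating. The Gapdh and beta-actin ratios above separate the same arrays, and the positions of the probe sets are not known here. Over 15 of the genes the dimmer probe set differed from the brighter by a median of 0.072 (interval -0.40 to 0.41), which decides nothing without those positions. Regulation of single genes by the coating stays open as untested.

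The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The coating split gave 877 large differences without overlap and the highest of the others gave 907, so 2 of 3 splits gave as many. For lists past the threshold with the preset correlation the values were 8 and 10, again 2 of 3 splits. The remaining split gave 349 large differences and 1 list. The split with the higher values put the arrays numbered 1 against those numbered 2, and there the sterol list passed too (camera's Benjamini-Hochberg adjusted p = 4.10e-06). The labels do not say whether the number marks a batch.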

How the results depend on the processing

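Replicate numbers are shared by the groups, but the labels give them no meaning, and 2 pairs are too few to show pairing; same-numbered arrays' deviations from their group means correlated at 0.271 across probe sets. With the replicate block, limma's Benjamini-Hochberg threshold was passed by 234 probe sets, 72 higher and 162 lower, and by 31 of 63 named probe sets. The block also put the hypertrophy list past it (camera's Benjamini-Hochberg adjusted p = 0.0173) and the neural list outside (0.0518), and changed no other list's call.

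The number of probe sets past the threshold was 0 under every other alternative with all 4 arrays, and ran from 0 to 459 with 1 array left out. Large differences without overlap numbered 1586 (697 higher, 889 lower) with no filter, 338 (121 and 217) with the stricter filter, 355 (88 and 267) with the offset and, in a setting chosen after seeing the data, 538 (252 and 286) with the brightest probe set per named gene. With 1 array left out they ran from 974 to 2211, with 419 to 821 higher and 555 to 1390 lower. The number of tested probe sets is not the whole account of the filter's effect. Large differences were 338 of 6346 probe sets with the stricter filter, a lower share than 877 of 9519 in the main fit. Fewer arrays loosen the overlap rule, and for the other values given here the cause was not tested.

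Of the 8 lists past the threshold, 0 passed with an estimated correlation, where camera's Benjamini-Hochberg adjusted p was 0.652 for sterol, matrix, immediate-early, proteasome, fibroblast and leukocyte genes, 0.711 for neural and 0.744 for fatty acid oxidation genes. That correlation was 0.312 for sterol, 0.686 for neural, 0.284 for fatty acid oxidation, 0.174 for fibroblast, 0.144 for proteasome and 0.102 for leukocyte genes. For matrix (-0.0065) and immediate-early genes (-0.0135) it lay below the preset 0.01. In fry 0 passed, at Benjamini-Hochberg adjusted p = 0.565 for sterol, matrix, proteasome and leukocyte, 0.325 for immediate-early, 0.638 for fibroblast, 0.643 for neural and 0.732 for fatty acid oxidation genes. On the deposited scale camera's Benjamini-Hochberg adjusted p was 0.0525 for matrix, 0.129 for fatty acid oxidation, 0.120 for fibroblast and 0.112 for neural genes. Without a filter 5 lists passed, with 0.108 for fatty acid oxidation, 0.162 for leukocyte and 0.775 for neural genes, and the mean over all probe sets gave 0.269 for neural genes. With 1 array left out, 2 to 9 lists passed. The adjusted p then ran from 6.76e-06 to 0.423 for matrix, 0.000648 to 0.115 for immediate-early, 2.66e-05 to 0.640 for fatty acid oxidation, 5.87e-05 to 0.211 for proteasome, 4.81e-07 to 0.423 for fibroblast, 0.00144 to 0.553 for leukocyte and 0.0121 to 0.289 for neural genes. The sterol list passed on the deposited scale, without a filter, without a floor, with the block, with the mean over all probe sets and with any 1 array left out. Counted but not followed list by list, 9 lists passed with arrays shifted to the same median, 7 with the stricter filter and 8 with the offset. Of 88 values for the 8 lists, all kept their direction and 40 missed the threshold. Lists that had not passed did so in 17 of 297 values, the ribosomal protein list at 1.72e-24 and the respiratory chain list at 9.13e-05 on the deposited scale among them.

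Of 766 values of named probe sets, 705 kept direction and side, 57 newly passed and 4 turned in sign. With 1 array left out the brighter Myh7 probe set ran from -0.065 (without control replicate 1) to 0.286, Myh6 from -0.38 (without fibronectin replicate 1) to 0.856, and C1qa from -0.22 (without control replicate 1) to 0.417, with -0.061 without fibronectin replicate 1. A named probe set that a changed filter left out has no value there. About 20% of values lay at the floor by its definition, so that share does not measure signal over background. Dim values were coarsest on fibronectin replicate 2, where 1 step was 19.5 times that of control replicate 1.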

Other observations

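No test in this part was chosen after the results were seen. Other gene groups gave no call with the preset correlation, and the adjusted p-values here are camera's after Benjamini-Hochberg adjustment. Ribosomal protein genes were higher on fibronectin for 25 of 39 measured members, with a median of 0.13 (adjusted p = 0.182), and the list passed on the deposited scale at 1.72e-24 and with the mean over all probe sets at 0.0455. Cell cycle genes were higher for 29 of 42, with a median of 0.22 (adjusted p = 0.259). RNA processing and splicing genes were lower for 21 of 34, with a median of -0.07 (adjusted p = 0.149). Matrix remodelling genes, such as proteases and cross-linkers, were lower for 14 of 25 (adjusted p = 0.268), and the list passed without control replicate 1 (0.0454) and without fibronectin replicate 2 (0.0378). Actin cytoskeleton genes and targets of serum response factor were lower for 23 of 41 (adjusted p = 0.259). That list passed, lower, with the mean over all probe sets (0.0203), without control replicate 1 (0.00551) and without fibronectin replicate 2 (0.0378), and its direction turned to higher on the deposited scale, without control replicate 2 (0.689) and without fibronectin replicate 1 (0.977). Inflammatory genes were lower for 19 of 27, growth factor and insulin pathway genes for 18 of 30, apoptosis regulators for 17 of 26 and hypoxia targets for 12 of 22, each at adjusted p = 0.259. The growth factor list passed with the mean over all probe sets (0.0457) and the apoptosis list without fibronectin replicate 2 (0.0303), while the apoptosis list turned to higher without fibronectin replicate 1 (0.977).

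Respiratory chain and citric acid cycle genes had a median of 0.08 over 59 members (adjusted p = 0.925), and the list passed on the deposited scale at 9.13e-05. Glycolysis genes had a median of -0.05 over 26 (adjusted p = 0.911), with the test's direction turned on the deposited scale. Medians were 0.11 over 31 endoplasmic reticulum chaperone genes (adjusted p = 0.773), 0.09 over 28 heat shock genes (adjusted p = 0.903), 0.06 over 46 translation genes (adjusted p = 0.903) and 0.21 over 23 interferon response genes (adjusted p = 0.903). Genes of transforming growth factor signalling had a median of -0.15 over 35 (adjusted p = 0.724). Natriuretic and calcineurin signalling genes had a median of 0.03, a mean of -0.13 and a lower direction in the test over 21 (adjusted p = 0.419). Antioxidant genes had a median of 0.002, a mean of 0.014 and a lower direction in the test over 35 (adjusted p = 0.975), turned on the deposited scale. The direction also turned in at least 1 fit with 1 array left out for all of these lists except endoplasmic reticulum chaperones and natriuretic and calcineurin signalling.

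Among markers of other cell types, endothelial genes had a median of -0.14 over 6 measured members (adjusted p = 0.903) and smooth muscle genes 0.13 over 14 (adjusted p = 0.903). Epicardial genes had a median of 0.25 over 8 (adjusted p = 0.903). Atrial myocyte genes had a median of -0.06, a mean of 0.05 and a higher direction in the test over 10 (adjusted p = 0.950). Erythroid genes, with 4 measured members, were not tested and had a median of 0.38. The direction of each of the 4 tested lists turned in at least 1 fit with 1 array left out.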
